A study of Homo sapiens with 9 samples.

How the data were processed

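Messenger RNA from U2OS cells was measured by RNA sequencing in 9 libraries, 3 each from wild-type cells on vehicle, wild-type cells on palbociclib and PERK knockout cells on palbociclib. Per the labels' protocols, RNA was column purified, mRNA was captured on poly-T beads and fragmented, and cDNA was primed with random hexamers. No step that marks the strand is given in the sources used here. The deposited values are raw counts of reads per gene, whole numbers in 1 column per library, not normalized and not pooled over replicates. Per the submitters' processing notes the tools were CASAVA, FastQC, Trim Galore, STAR 2.7.9a and DESeq2, with the build hg38, in no stated role or order. The counter, its strand setting and the annotation release are not given in the sources used here, so reads from antisense, overlapping or near-identical genes may be divided in ways that cannot be checked. Poly(A) capture leaves out most RNA without a tail, so replication-dependent histone mRNAs are measured only in part.

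The table held 70116 versioned Ensembl gene IDs, of which 62700 had a symbol. Positions came from GENCODE release 29 on GRCh38, matched by ID without its version for 58261 IDs. Counts that name no gene were not among the values tested, and IDs without a symbol took 0.1 to 0.12% of counts. Totals ran from 33674039 to 42577874 counts per library, with 29276 to 30540 genes at 1 count or more. The 10 most counted genes took 5.07 to 6.36% of counts. No pair of replicates differed by as little as sampling noise (chi-square per degree of freedom 3.45 to 10.7 over genes with at least 20 counts).

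Counts were tested with the edgeR quasi-likelihood F test (edgeR 4.0.16, limma 3.58.1, R 4.3.3; Python 3.11.15 and matplotlib 3.10.9 for preparation and figures), with robust fitting, TMM factors (0.977 to 1.01) and the default low-count filter on groups. The filter left 19408 genes, holding 99.91% of counts. All 9 libraries entered 1 model of 3 groups with 6 residual degrees of freedom. The biological coefficient of variation was 5.99%. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. CPM values are scaled by TMM factors and given as mean ± SD, and log2 fold changes with their SE. The comparisons were palbociclib against vehicle in wild-type cells, knockout against wild-type cells on palbociclib, and knockout cells on palbociclib against wild-type cells on vehicle. The design, the alternatives, the 29 gene lists and the rule for named genes were set before the data were examined.

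The lists, with 777 entries, covered E2F targets, G2 and mitosis genes, replication-dependent histones, targets of ATF4 and CHOP, aminoacyl-tRNA synthetases, the ATF6 and IRE1 arms, p53 targets, senescence-associated secretory factors, NF-kappaB feedback targets, interferon-stimulated genes, antigen processing, lysosome, autophagy, extracellular matrix, osteoblast differentiation, YAP and TEAD targets, cholesterol synthesis, NRF2 targets, hypoxia and glycolysis, cytosolic ribosomal proteins, ribosome biogenesis and oxidative phosphorylation. Checks of RNA quality and handling used mitochondrially encoded mRNAs, nuclear retained RNAs, and immediate early and heat shock genes. Markers of epithelial, haematopoietic and endothelial cells stood for other cell types. Each list was tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. Camera with an estimated correlation and fry, which does not compare a list with other genes, were run beside it.

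Named genes were EIF2AK3, CDK4, CDK6, CCND1, RB1, CDKN1A, ATF4 and DDIT3, and the 5 highest and 5 lowest called genes (3 and 3 in the last comparison) with a mean of at least 5 CPM, non-overlapping ranges and a regular symbol. For each called list the 2 members that moved most in its direction, at a mean of at least 1 CPM, were added, as were the 3 genes that moved back most in the knockout. Some items are not reported here. CCNE1, IL6, H4C3 and PAGE2, and the genes named only in the closing observations, were chosen after their values were seen.

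The set numbers in the labels are shared between groups. Deviations from group means were compared over 12932 genes with a mean log2 CPM above 1. All 9 pairs of libraries with the same number correlated at 0.18 to 0.54, pairs with different numbers at -0.4 to 0.071, and each of the 9 libraries was closest to its own set in both other groups. Over all tested genes the same pairs correlated at 0.03 to 0.22, with 6 of 9 above 0.1, and different sets at no more than 0.044. The numbers were therefore taken to pair the libraries, a decision made from these correlations and not from any label. The main model had been set beforehand and leaves this pairing out. Unless the block is named, p-values, SEs and counts come from that model, and their spread includes differences between sets. A model with the set as a block was fitted as an alternative.

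Genes were simulated from the real means and library sizes with 1.25-, 1.5-, 2- and 3-fold changes. At each size 46 to 50 of the tested genes were changed, far fewer than were called in the data. The shares recovered are therefore not the sensitivity of the real comparisons. For palbociclib in wild-type cells (19083 genes) 42.9, 54, 84.8 and 84% of changed genes were recovered, with 11 unchanged genes called. For knockout against wild type (19052 genes) the values were 40.8, 66, 73.5 and 93.9%, with 9 unchanged genes called, and for the last comparison (19076 genes) 50, 61.2, 72 and 92%, with 6. A list shifted by 0.3 on the log2 scale was called in each comparison, beside 1, 0 and 1 of 28 unshifted lists. Genes were drawn independently of each other in these runs. They therefore do not gauge the list test where members are correlated, such as the E2F targets (estimated correlation 0.493 for the drug in wild-type cells).

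Alternatives were other scalings, no filter or a stricter one, limma-voom, DESeq2 1.42.0, the 6 compared libraries alone, the replicate block, each library left out, an estimated correlation and fry. For regional shifts, protein-coding genes were grouped in 269 windows of 10 Mb with at least 15 genes. The median of the other genes of a window was subtracted from each gene before a camera test on z-scores (log2 fold change over its SE), not on ranks. That subtraction, the restriction to windows near 0, the test of window medians on GC content and length, the lysosome list without CTSB and the block with an estimated correlation were chosen after seeing the data. For overlaps, 20 simulations drew unchanged groups that shared libraries.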

Results

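Poly(A)-selected RNA was profiled in U2OS, an established human osteosarcoma cell line, and in a derivative of it in which PERK had been targeted with CRISPR/Cas9. PERK, encoded by EIF2AK3, is a kinase of the endoplasmic reticulum membrane that phosphorylates the translation factor eIF2α and so starts one branch of the integrated stress response. Palbociclib inhibits CDK4 and CDK6, the kinases that phosphorylate the retinoblastoma protein before S phase. There were 9 libraries in 3 groups of 3: wild-type cells given vehicle, wild-type cells given palbociclib, and knockout cells given palbociclib, with 4 days of drug. Vehicle-treated knockout cells were not analysed here, so the difference between genotypes was measured on the drug only, and whether the response to the drug itself differed between genotypes was not tested. Total counts per library ran from 33674039 to 42577874, with a mean of 38768641 ± 2635705 in the vehicle group, 36113321 ± 2152770 in the wild-type palbociclib group and 39599036 ± 3687538 in the knockout group (SD, n = 3). After a filter on low counts, 19408 genes were tested. Libraries of one group correlated at 0.995 or above across genes, against 0.965 to 0.985 between groups. The labels give each library a set number but do not say whether sets were separate cultures, so the p-values measure the spread between these libraries, which may be technical.

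The targeted gene was measured first. EIF2AK3 (ENSG00000172071.15, chromosome 2, 88556741 to 88627576 on GRCh38, a protein-coding gene) stood at 33.1 ± 1.6 CPM (counts scaled to library size) in vehicle-treated and 34.8 ± 2.6 in palbociclib-treated wild-type cells (mean ± SD, n = 3 here and below). In the knockout it stood at 18.7 ± 0.97, and its 3 libraries (19.7, 18.7 and 17.8) all lay below every wild-type library (31.7 to 36.8). The knockout level was 53.9% of the wild-type level on the drug (log2 fold change -0.89 ± 0.068 SE, edgeR adjusted p = 5.98e-09). EIF2AK3 mRNA was therefore reduced but still present in the libraries labelled knockout. PERK protein was not measured in these data, and an edited gene can keep its mRNA. Palbociclib did not move EIF2AK3 past the threshold in wild-type cells (log2 fold change 0.07 ± 0.066, edgeR adjusted p = 0.417).

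**Figure D1:**
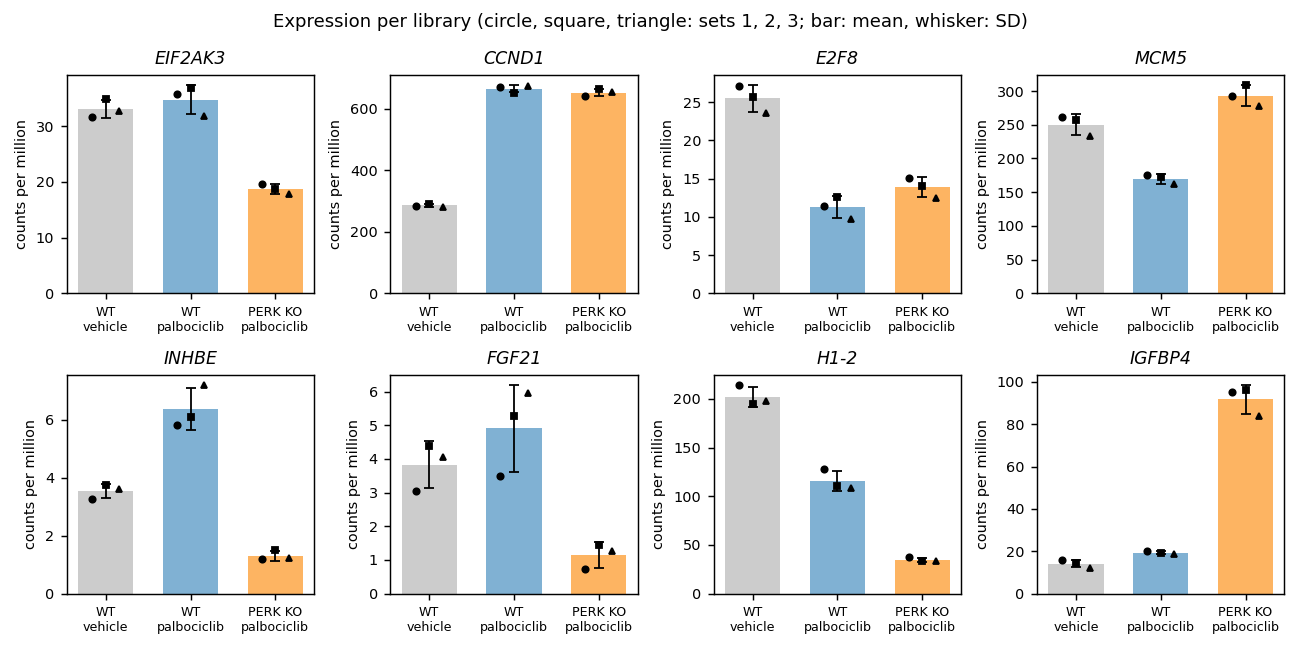
Library-scaled counts (CPM) of 8 genes in each of the 9 libraries, by group (bars, mean of 3 libraries; whiskers, SD; symbols, sets 1 to 3). EIF2AK3 falls from 34.8 to 18.7 CPM between wild-type and knockout cells on palbociclib, CCND1 rises from 286 to 665 CPM with palbociclib in wild-type cells, and MCM5 stands at 250, 170 and 293 CPM in the 3 groups.

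The first comparison asked which mRNAs the CDK4/6 inhibitor changed in wild-type cells. Genes of DNA replication and mitosis fell together. Of 49 measured members of the DNA replication and S phase list, targets of the E2F factors that the retinoblastoma protein restrains, 48 fell and 1 rose (48 and 1 adjusted over the list alone), with a median log2 fold change of -0.64. E2F8, a repressor of the E2F family, fell from 25.5 ± 1.7 to 11.3 ± 1.5 CPM (log2 fold change -1.18 ± 0.093) and GINS2, part of the replicative helicase, fell from 88.3 ± 8.0 to 44.7 ± 2.3 (-0.98 ± 0.062). CCNE1, encoding cyclin E1, was the member that rose (0.18). Of the 41 genes of the G2 and mitosis list, 40 fell and 0 rose (41 and 0 adjusted over the list alone), with a median of -0.57. Among them CCNA2, encoding cyclin A2, fell from 236 ± 11 to 131 ± 13 CPM and the mitotic kinase AURKB from 68.6 ± 3.4 to 39 ± 3.6. Both lists passed the camera test with a preset correlation (adjusted p = 5.0e-41 and 3.3e-21). Neither passed when the correlation between members was estimated from the libraries (adjusted p = 0.0885 and 0.261 with an estimated correlation).

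CCND1, encoding cyclin D1, the partner of CDK4 and CDK6, rose from 286 ± 5.7 to 665 ± 12 CPM with the drug (log2 fold change 1.22 ± 0.046, edgeR adjusted p = 1.5e-13). CDK6 rose (0.38 ± 0.056, edgeR adjusted p = 1.71e-05) and CDK4 fell (-0.18 ± 0.045, edgeR adjusted p = 0.00254). RB1, encoding the retinoblastoma protein, fell (-0.33 ± 0.061, edgeR adjusted p = 0.000207), and CDKN1A, encoding the kinase inhibitor p21, rose (0.28 ± 0.055, edgeR adjusted p = 0.000316). The stress response factors ATF4 (0.07 ± 0.046, edgeR adjusted p = 0.212) and DDIT3 (-0.21 ± 0.14, edgeR adjusted p = 0.239) did not pass the threshold.

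Secreted, lysosomal and matrix genes rose. In the list of senescence-associated secretory factors 17 of 31 measured members rose and 1 fell (18 and 1 adjusted over the list alone), with a median log2 fold change of 0.61. The matrix protease MMP3 rose from 14.3 ± 4.3 to 36.9 ± 9.7 CPM. The cytokine IL6 rose but was near the floor of detection in all groups (0.222 ± 0.0717 CPM with vehicle and 0.52 ± 0.146 with palbociclib). Of 37 lysosomal genes of the CLEAR network, 27 rose and 3 fell (27 and 3 adjusted over the list alone), with a median of 0.45. The cholesterol transporter NPC2 (0.86 ± 0.083) and the fucosidase FUCA1 (0.78 ± 0.079) moved most among the more abundant members. Of 23 autophagy genes 14 rose and 1 fell (15 and 1 adjusted over the list alone; median 0.21), including GABARAPL1 (1.21 ± 0.053) and TP53INP2 (0.90 ± 0.054). Of 30 genes for collagens and extracellular matrix 20 rose and 0 fell (21 and 0 adjusted over the list alone; median 0.59), including the proteoglycan LUM (1.63 ± 0.088) and the collagen chain COL5A1 (1.40 ± 0.12). The camera adjusted p was 3.45e-08 for the secretory list, 3.7e-13 for lysosome, 2.3e-08 for autophagy and 9.5e-14 for matrix. With an estimated correlation none of these 4 lists passed (adjusted p = 0.0885, 0.0885, 0.0885 and 0.261 with an estimated correlation). With the set number as a replicate block and an estimated correlation, the lysosome list alone passed (camera adjusted p = 0.0255).

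Shifts were also called in 6 further lists. In the IRE1 and XBP1s list, genes of another branch of the unfolded protein response, 16 of 24 members rose and 2 fell (18 and 2 adjusted over the list alone; median 0.20, camera adjusted p = 4.1e-07), with the autophagy factor WIPI1 at 1.62 ± 0.061 and the retrieval receptor KDELR3 at 0.79 ± 0.052. Of 29 targets of p53, 14 rose and 5 fell (14 and 5 adjusted over the list alone; median 0.10, camera adjusted p = 0.0155), with TP53INP1 at 1.40 ± 0.15 and ZMAT3 at 0.92 ± 0.059. Of 28 hypoxia and glycolysis genes 12 rose and 1 fell (12 and 2 adjusted over the list alone; median 0.16, camera adjusted p = 0.00732), with P4HA1 at 1.04 ± 0.16 and PDK1 at 0.93 ± 0.18. Of 19 YAP and TEAD targets 10 rose and 1 fell (10 and 1 adjusted over the list alone; median 0.17, camera adjusted p = 0.0276), with CCN2 at 0.68 ± 0.066 and CCN1 at 0.53 ± 0.060. This last call was lost without wild-type vehicle library 3 (camera adjusted p = 0.0503). Of 22 genes of cholesterol synthesis 11 fell and 0 rose (11 and 0 adjusted over the list alone; median -0.27, camera adjusted p = 0.0024), with MVK at -0.63 ± 0.094 and ACAT2 at -0.51 ± 0.088. Of 28 genes of ribosome biogenesis 19 fell and 1 rose (19 and 1 adjusted over the list alone; median -0.24, camera adjusted p = 1.0e-04), with NOP56 at -0.56 ± 0.050 and NOP58 at -0.40 ± 0.046. With an estimated correlation none of the 6 lists passed (adjusted p = 0.0885, 0.261, 0.452, 0.335, 0.536 and 0.394 with an estimated correlation, in the order given). Between sets, 50% of the hypoxia genes, 59.1% of the cholesterol genes, 66.7% of the matrix genes and 68.3% of the G2 and mitosis genes differed in the blocked model, against 8.07% of all tested genes. So did 100% of the mitochondrially encoded mRNAs, 55.6% of the nuclear retained RNAs and 50% of the NRF2 targets.

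The integrated stress response list, targets of ATF4 and CHOP, was not called with palbociclib in wild-type cells (13 of 39 members rose and 3 fell, 13 and 3 adjusted over the list alone; median 0.07, camera adjusted p = 0.164). It was called higher without a low-count filter (median 0.09, camera adjusted p = 0.00852) and by fry (0.0452), but not with the correlation estimated (adjusted p = 0.721 with an estimated correlation). The remaining lists were not called either. Their camera adjusted p was 0.892 for aminoacyl-tRNA synthetases, 0.286 for the ATF6 arm and ER chaperones, 0.849 for NF-kappaB feedback targets, 0.0837 for interferon-stimulated genes, 0.909 for antigen processing, 0.421 for osteoblast differentiation and 0.849 for NRF2 targets. It was 0.909 for ribosomal proteins, 0.286 for replication-dependent histones and 0.0504 for oxidative phosphorylation, of which 14 of 30 genes fell and 1 rose (14 and 1 adjusted over the list alone). The oxidative phosphorylation list was called lower without vehicle library 1 (0.0225) or 2 (0.0328), wild-type palbociclib library 2 (0.04) or knockout library 2 (0.0472), with limma-voom (0.0174) and without a low-count filter (0.00478), and the interferon list higher without wild-type palbociclib library 3 (0.0195). Neither was called with the correlation estimated (adjusted p = 0.536 and 0.394 with an estimated correlation). Markers of RNA quality and handling did not pass: mitochondrially encoded mRNAs (camera adjusted p = 0.612), immediate early and heat shock genes (0.612) and nuclear retained RNAs (0.582). Markers of other cell types, with a median level of 3.46, 1.68 and 1.97 CPM in the order given, gave camera adjusted p = 0.0556 for epithelial genes (0.0222 with the replicate block, 0.0428 without wild-type palbociclib library 3 and 0.0472 without knockout library 2), 0.13 for haematopoietic genes and 0.0586 for endothelial genes. Epithelial genes missed with the correlation estimated (adjusted p = 0.261 with an estimated correlation) and when the block was added to that (0.193).

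Over all 19408 genes, 8478 changed with palbociclib in wild-type cells (4141 higher, 4337 lower, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), 782 of them at least 2-fold higher and 286 at least 2-fold lower. The highest were ODAPH (0.805 ± 0.23 to 12.2 ± 1.4 CPM, log2 fold change 3.91), the metalloproteinase PAPPA2 (3.23 ± 0.13 to 19.8 ± 1.0, 2.61), TXNIP, a thioredoxin-binding arrestin (9.62 ± 4.1 to 53.8 ± 22, 2.50), the serine protease FAP (4.92 ± 0.14 to 25.9 ± 1.2, 2.40) and PIK3IP1 (11.6 ± 2.6 to 55 ± 3.8, 2.25). The lowest were TNFAIP6 (-1.66), the receptor ERBB3 (9.34 ± 0.30 to 2.95 ± 0.22, -1.66), the Wnt deacylase NOTUM (-1.54), the transporter SLCO4A1 (-1.40) and CCDC144NL (-1.34). CCDC144NL has close sequence relatives, so its count is uncertain. TNFAIP6 differed between sets in the blocked model (edgeR adjusted p = 3.42e-09). Its call (edgeR adjusted p = 0.0377) was lost without vehicle library 2 or 3, without wild-type palbociclib library 1, 2 or 3, or without knockout library 2, at adjusted p between 0.0626 and 0.108, and with only the 6 libraries compared (0.0639).

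The second comparison asked how knockout cells differed from wild-type cells when both were on palbociclib. Targets of the integrated stress response were lower in the knockout. Of 39 measured members 30 were lower and 1 higher (33 and 1 adjusted over the list alone), with a median log2 fold change of -0.34. INHBE, an inhibin subunit, stood at 6.36 ± 0.73 CPM in wild-type and 1.31 ± 0.17 in knockout cells (-2.29 ± 0.15, edgeR adjusted p = 7.58e-10), and the hormone FGF21 at 4.9 ± 1.3 and 1.15 ± 0.38 (-2.11 ± 0.25, edgeR adjusted p = 2.6e-05). ATF4 itself was slightly lower (-0.17 ± 0.046, edgeR adjusted p = 0.00735). DDIT3, encoding CHOP, had a log2 fold change of -0.34 ± 0.14 (edgeR adjusted p = 0.0838, 0.0128 with the replicate block, and 0.0372 without wild-type palbociclib library 1). The list passed the camera test (adjusted p = 9.2e-20) and narrowly missed with the correlation estimated (adjusted p = 0.0557 with an estimated correlation). With the block and an estimated correlation it also missed (adjusted p = 0.19). Subtracting the median shift of each gene's 10 Mb neighbourhood, described below, left the median at -0.35. The other arms of the unfolded protein response did not pass, namely the ATF6 arm (5 higher and 1 lower of 19, camera adjusted p = 0.386) and the IRE1 and XBP1s arm (2 higher and 5 lower of 24, camera adjusted p = 0.312). Nor did the cytosolic aminoacyl-tRNA synthetases, a list tested apart from the stress response targets (3 higher and 8 lower of 18, camera adjusted p = 0.312).

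Genes of DNA replication were higher in the knockout on the drug. Of 49 members 31 were higher and 3 lower (33 and 3 adjusted over the list alone; median 0.18, camera adjusted p = 2.8e-06), but the call was lost with the correlation estimated (adjusted p = 0.89 with an estimated correlation). The helicase subunit MCM5 stood at 170 ± 6.6 CPM in wild-type and 293 ± 16 in knockout cells (0.79 ± 0.055), and at 250 ± 15 in vehicle-treated wild-type cells. BRCA1 stood at 80.5 ± 5.1 and 117 ± 5.7 (0.54 ± 0.055). G2 and mitosis genes were not called (3 higher and 5 lower of 41, 2 and 4 adjusted over the list alone; median -0.07, camera adjusted p = 0.312). Without wild-type palbociclib library 3 or knockout library 1 that list was called lower (camera adjusted p = 0.00489 and 0.000473), and with all libraries it missed with the correlation estimated (adjusted p = 0.903 with an estimated correlation). CCND1 (-0.03 ± 0.045) and RB1 (-0.10 ± 0.062) did not pass the threshold, with RB1 passing without wild-type palbociclib library 3 (edgeR adjusted p = 0.0172). CDKN1A was higher (0.33 ± 0.055, edgeR adjusted p = 0.000104), in a window of chromosome 6 whose other genes had a median of -0.36, and CDK6 lower (-0.23 ± 0.056, edgeR adjusted p = 0.00465). CDK4 had a log2 fold change of 0.10 ± 0.045 (edgeR adjusted p = 0.0998, and 0.0388 with the replicate block).

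**Figure D2:**
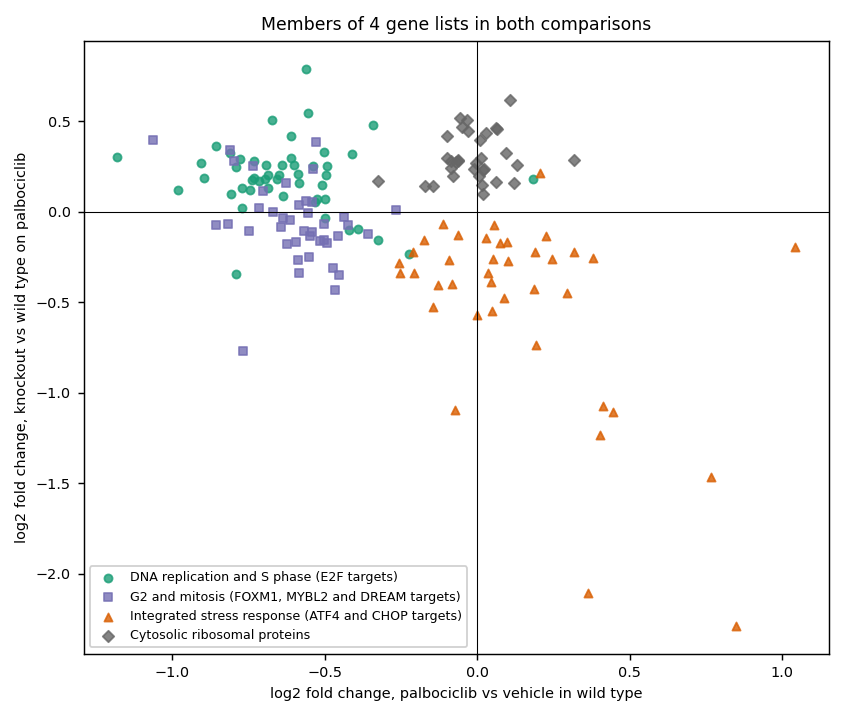
Each point is 1 gene of 4 lists, with its log2 fold change for palbociclib against vehicle in wild-type cells on the x axis and for knockout against wild-type cells on palbociclib on the y axis. E2F targets lie at a median of -0.64 on x and 0.18 on y, and integrated stress response targets at 0.07 on x and -0.34 on y.

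Replication-dependent histone mRNAs were lower in the knockout. Of 15 measured members 10 were lower and 1, H4C3, was higher (11 and 1 adjusted over the list alone), with a median of -0.89. H1-2, encoding a linker histone, stood at 116 ± 10 CPM in wild-type and 34.8 ± 2.1 in knockout cells (-1.74 ± 0.065), and H2BC4 at 2.12 ± 0.39 and 0.553 ± 0.082 (-1.92 ± 0.23). The call held with the correlation estimated (camera adjusted p = 2.5e-18, and 0.0221 with an estimated correlation) and was lost when the block was added (adjusted p = 0.0611). Histone genes have near-identical copies and mRNAs that mostly lack a poly(A) tail, so their counts from poly(A)-selected RNA are uncertain. Cytosolic ribosomal protein mRNAs were higher: 31 of 33 rose and 0 fell (32 and 0 adjusted over the list alone; median 0.28, camera adjusted p = 9.1e-17, and 0.586 with an estimated correlation). RPL23 stood at 598 ± 24 and 917 ± 6.3 CPM (0.62 ± 0.047) and RPL27 at 468 ± 39 and 670 ± 13 (0.52 ± 0.060). Of 30 nuclear-encoded oxidative phosphorylation genes 16 were higher and 3 lower (17 and 4 adjusted over the list alone; median 0.16, camera adjusted p = 0.000813, and 0.611 with an estimated correlation). ATP5MC1 (0.73 ± 0.048) and UQCRC2 (0.59 ± 0.052) moved most.

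Epithelial markers, at a median of 3.46 CPM over all libraries, were lower (6 of 14 lower and 0 higher, 6 and 0 adjusted over the list alone; median -0.59, camera adjusted p = 1.5e-05). The call held with the correlation estimated (adjusted p = 0.0355 with an estimated correlation) and was lost when the block was added (adjusted p = 0.105). CLDN1, a tight junction protein, stood at 17.7 ± 2.8 and 9.47 ± 0.43 CPM (-0.90 ± 0.11), and the cadherin CDH1 at 3.63 ± 0.36 and 2.13 ± 0.22 (-0.77 ± 0.15). The lysosome list was called lower on 37 members (4 higher and 12 lower, 4 and 14 adjusted over the list alone; median -0.07, camera adjusted p = 0.000179, and 0.586 with an estimated correlation), with the cathepsin CTSF at -0.60 ± 0.10. Without CTSB its unadjusted camera p was 0.0439. Haematopoietic (camera adjusted p = 0.574) and endothelial (0.717) markers were not called. The handling and RNA quality lists also missed: mitochondrially encoded mRNAs (camera adjusted p = 0.744), immediate early and heat shock genes (0.574) and nuclear retained RNAs (0.801).

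The other lists were not called between genotypes. Camera adjusted p was 0.133 for p53 targets, 0.408 for the secretory factors, whose median (-0.08) and mean (0.09) differed in sign, 0.127 for NF-kappaB feedback targets and 0.717 for autophagy. It was 0.806 for interferon-stimulated genes, with a median of 0.14 and a mean of -0.03, and 0.574 for antigen processing. It was 0.384 for matrix genes (0.0371 with the replicate block and 0.0144 without knockout library 1), 0.386 for hypoxia genes (0.0371 with the replicate block), 0.574 for osteoblast differentiation and 0.801 for YAP and TEAD targets. With the block and an estimated correlation neither matrix nor hypoxia genes passed (adjusted p = 0.817 for both). It was 0.191 for cholesterol synthesis, which was called lower without wild-type palbociclib library 3 (0.0112) or knockout library 1 (0.0173) and missed with all libraries and the correlation estimated (adjusted p = 0.89 with an estimated correlation). It was 0.758 for NRF2 targets and 0.386 for ribosome biogenesis.

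**Figure D3:**
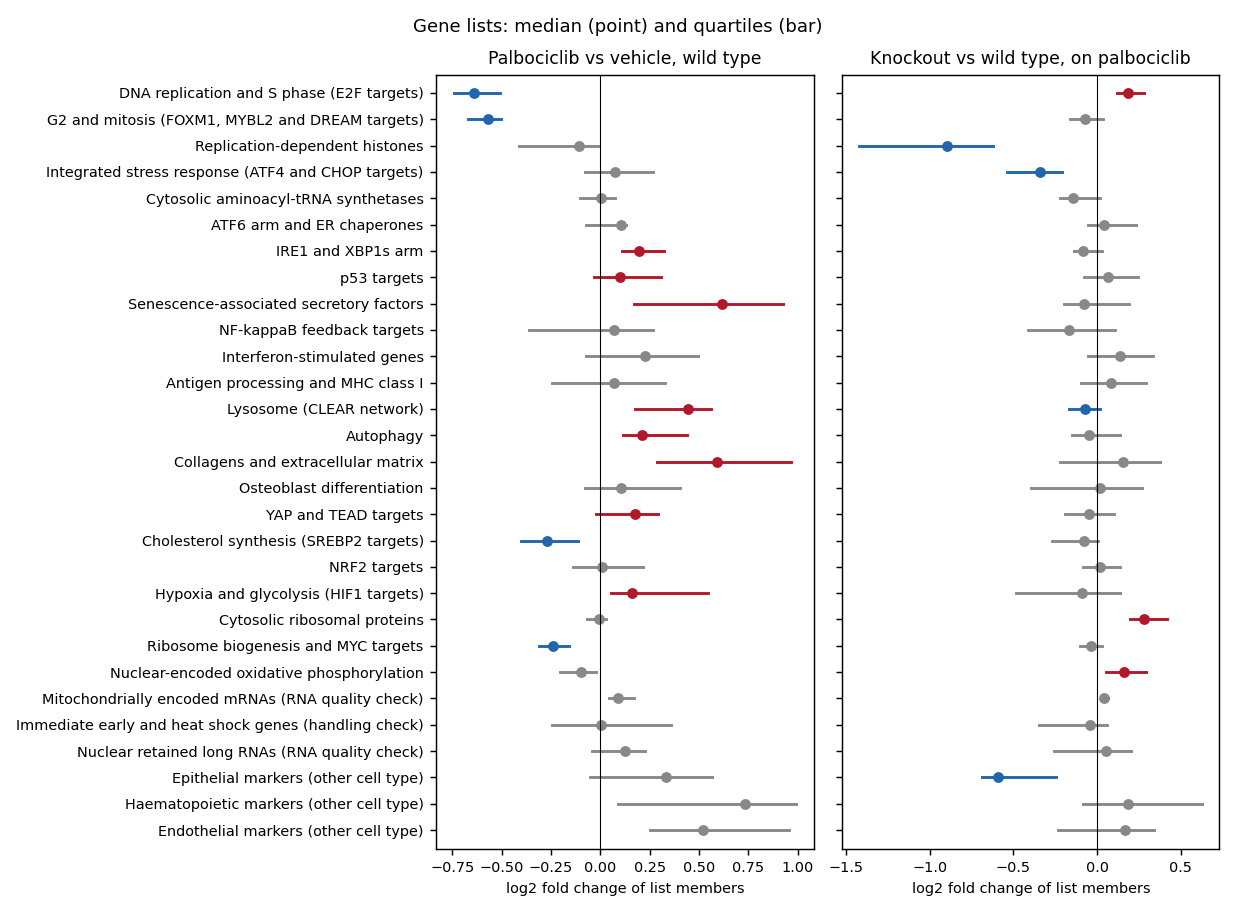
Median (point) and quartiles (bar) of the log2 fold changes of the measured members of 29 gene lists, for palbociclib against vehicle in wild-type cells (left) and knockout against wild-type cells on palbociclib (right); the horizontal scales differ. Red and blue mark lists called higher and lower by camera with a preset correlation of 0.01, grey the rest: 8 and 4 lists on the left, 3 and 4 on the right.

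In all, 5419 of 19408 genes differed between knockout and wild-type cells on palbociclib (2896 higher and 2523 lower, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), 234 of them at least 2-fold higher and 351 at least 2-fold lower. Some of the lowest were close to absent. CTSB, encoding the lysosomal protease cathepsin B (chromosome 8, 11842524 to 11869448), stood at 40.8 ± 2.3 CPM in wild-type and 0.439 ± 0.087 in knockout cells (log2 fold change -6.54 ± 0.12). PAGE2B (chromosome X, 55075063 to 55078909) fell from 82.7 ± 3.8 to 0.137 ± 0.13 CPM (-9.12 ± 0.19). Its near-identical neighbour PAGE2 was higher in the knockout (0.44), and reads shared between them make both counts uncertain. HSPB7, a small heat shock protein (-5.03 ± 0.21), BST2, an interferon-inducible membrane protein (-4.60 ± 0.15), and GTSF1 (-3.82 ± 0.12) were the others. The highest were DLX4 (1.97 ± 0.39 to 9.57 ± 0.85 CPM, 2.28 ± 0.14), IGFBP4, which binds insulin-like growth factors (19.4 ± 0.83 to 91.7 ± 6.7, 2.24 ± 0.077), TUBG2 (1.98 ± 0.12), HOXB2 (1.91 ± 0.12) and SLN, a regulator of the calcium pump (1.75 ± 0.13).

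Neighbouring genes shifted together in this comparison. DLX4, IGFBP4, TUBG2 and HOXB2 all lie on chromosome 17 between 40 and 50 Mb, where the median log2 fold change of the other protein-coding genes was 0.26. That is far below their own shifts, so the regional shift covers only a small part of them. The genes next to IGFBP4 had log2 fold changes of 0.0783 (RARA), 0.235 (TOP2A), 0.0798 (TNS4) and 0.523 (SMARCE1). RPL27 (0.52), ATP5MC1 (0.73) and BRCA1 (0.54) lie in the same window, and RPL23 (0.62) in the adjacent one (median 0.27). UQCRC2 (0.59) lies on chromosome 16 between 20 and 30 Mb, where the median of the other genes was 0.21. For these genes the regional shift is a larger part of the change. CTSB lies on chromosome 8 between 10 and 20 Mb, where the median of the other genes was -0.43, only a small part of its own shift. Over 269 windows of 10 Mb the medians had an SD of 0.15 in this comparison and 0.0669 for the drug in wild-type cells. The lowest window was on chromosome 1 from 160 to 170 Mb (-0.64 over 68 genes, of which 5.88% were above 0), and both windows from 0 to 20 Mb on chromosome 20 were close to it (-0.61 and -0.59). The highest was on chromosome 10 from 130 Mb (0.47 over 23 genes). Of 18067 genes with a window, 11830 lay in windows with a median within 0.1 of 0, and 22.5% of these were called in the test over all genes, against 40.9% of those in other windows. After subtraction of the window medians, a camera test on z-scores at the preset correlation still called the lists for E2F targets (median 0.24), histones (-0.73), stress response (-0.35), ribosomal proteins (0.26), oxidative phosphorylation (0.16) and epithelial markers (-0.55). It also called p53 targets higher (camera adjusted p = 0.0385, and 0.13 before subtraction) and NF-kappaB feedback targets lower (camera adjusted p = 0.0256, and 0.0319 before subtraction in the same test). Without subtraction neither passed with the correlation estimated (adjusted p = 0.781 for p53 and 0.89 for NF-kappaB targets with an estimated correlation), nor with the block added (0.345 and 0.817). The lysosome list was no longer called (camera adjusted p = 0.0672).

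**Figure D4:**
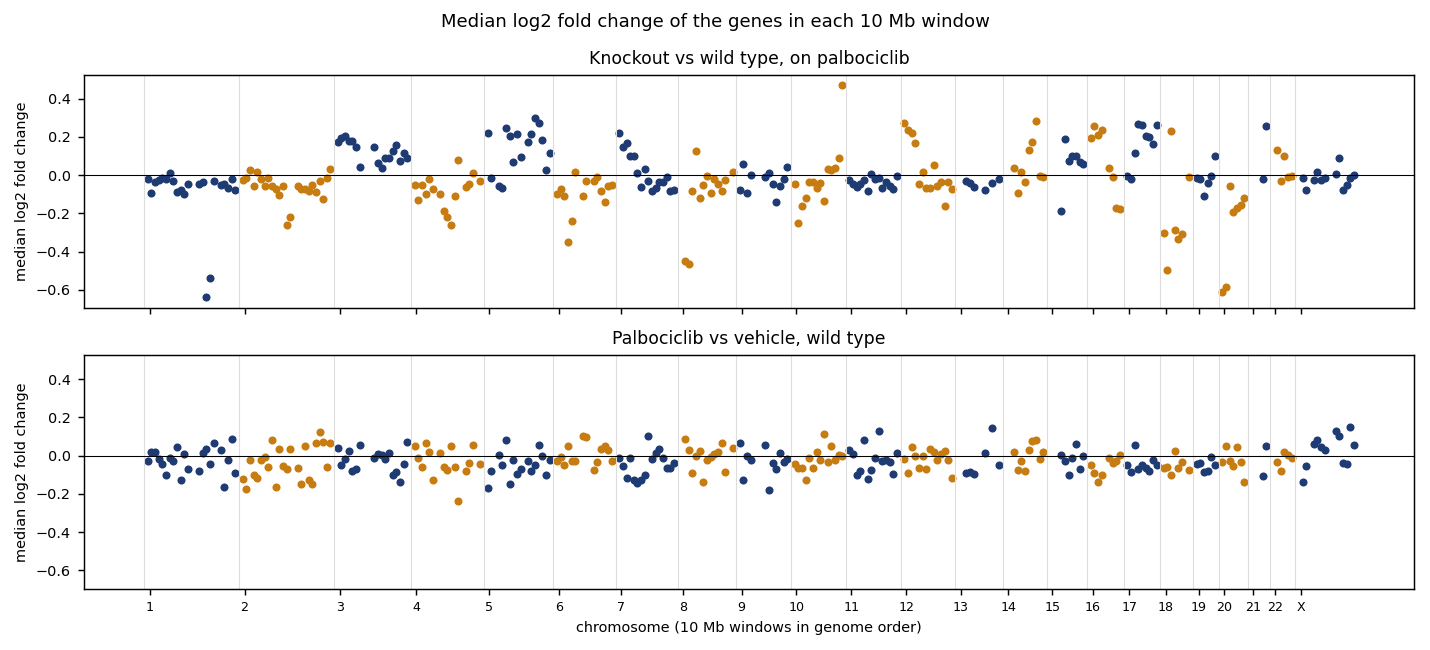
Median log2 fold change of the protein-coding genes in each of 269 windows of 10 Mb in genome order, with chromosomes in alternating colours, for knockout against wild-type cells on palbociclib (top) and palbociclib against vehicle in wild-type cells (bottom). The top panel reaches from -0.64 on chromosome 1 to 0.47 on chromosome 10, and runs of adjacent windows share a sign.

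Of the genes that rose with the drug in wild-type cells, 808 were lower and 747 higher in the knockout on the drug (1147 and 1088 with the replicate block). Of those that fell, 889 were higher and 536 lower (1291 and 853 with the replicate block). Independent lists without the block would share 538, 618, 647 and 564 genes in the same order. Simulated unchanged groups that shared the wild-type palbociclib libraries gave at most 1. Unchanged genes are seldom called in either comparison, so that value does not gauge the overlap to be met among changed genes. Both comparisons use those 3 libraries with opposite sign, and no run divided them between the comparisons, so part of the excess may come from sharing them. Across 13013 genes, which are not independent replicates, the log2 fold changes correlated at r = -0.08 (simulated -0.51; covariance -0.0114, simulated -0.00497). At 2-fold in both, 48 genes rose with the drug and were lower in the knockout, and HSPB7 (3.54 ± 0.95, 11.8 ± 1.1 and 0.362 ± 0.049 CPM in the 3 groups), OLR1 (3.23 ± 0.58, 9.15 ± 2.1 and 2.62 ± 0.41) and DNM3 (4.32 ± 0.31, 11.1 ± 0.82 and 3.96 ± 0.14) led them. DNM3 lies on chromosome 1 between 170 and 180 Mb, where the median of the other genes was -0.52. The reverse pattern at 2-fold held in 29 genes, none of which met the rule for naming a gene.

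Last, knockout cells on palbociclib were set against wild-type cells on vehicle, which mixes both differences. Genes of DNA replication (44 of 49 lower, 2 higher, 44 and 2 adjusted over the list alone; median -0.48) and of G2 and mitosis (39 of 41 lower, 0 higher, 40 and 0 adjusted over the list alone; median -0.67) stood below the vehicle level. Stress response targets did too (27 of 39 lower, 2 higher, 28 and 2 adjusted over the list alone; median -0.35), as did histones (13 of 15 lower, 0 higher, 14 and 0 adjusted over the list alone; median -1.27). Of ribosomal protein mRNAs 30 of 33 were higher and 0 lower (30 and 0 adjusted over the list alone; median 0.26). Camera adjusted p was 7.1e-14, 2.2e-17, 4.6e-06, 5.5e-11 and 2.4e-07 for these 5 lists. The adjusted p was 0.291, 0.291, 0.291, 0.0778 and 0.449 with an estimated correlation. In all 13 of 29 lists were called, 7 higher and 6 lower, and 0 with an estimated correlation. The other 8 were IRE1 and XBP1s, p53, secretory, lysosome, autophagy, matrix, cholesterol and ribosome biogenesis (adjusted p = 0.291, 0.281, 0.146, 0.393, 0.146, 0.291, 0.449 and 0.425 with an estimated correlation). The largest differences were in SLN (1.06 ± 0.23 to 11.5 ± 0.89 CPM, log2 fold change 3.44), TXNIP (9.62 ± 4.1 to 79.7 ± 19, 3.06) and ARRDC4, another arrestin (4.98 ± 0.70 to 36.4 ± 8.6, 2.87), and in PAGE2B (-8.55), CTSB (28 ± 1.4 to 0.439 ± 0.087 CPM) and GTSF1 (-3.86). ARRDC4 differed between sets in the blocked model (edgeR adjusted p = 8.12e-08), and TXNIP ranged from 35.1 to 77.9 CPM among the wild-type palbociclib libraries. In total 10036 genes differed (4983 higher, 5053 lower, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Fold changes of this comparison and of the drug in wild-type cells correlated at r = 0.715 across genes (simulated 0.499; covariance 0.154, simulated 0.00489), with the vehicle libraries shared.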

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

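The tests with window medians, without CTSB and with the block plus an estimated correlation were chosen only after the results were seen. The 187 values compared were tests of named genes and lists, and counts of calls. Tests had to keep their side of the threshold and, if called, their direction, and counts only had to stay within a fixed factor of the main value. Under RLE, upper-quartile or total-count scaling, or totals without the 10 most counted genes, all 187 met these limits, while 1, 2, 1 and 0 uncalled values changed sign. The median of all genes stayed within 0.1 of 0. All 97 values compared with DESeq2 met the same limits, and its adjusted p was NA for 19692, 20479 and 16541 of 40627 genes in the 3 comparisons. No called value changed direction under any alternative run. Without a low-count filter 13 lists were called between genotypes, the added ones being G2 and mitosis (camera adjusted p = 0.0302), aminoacyl-tRNA synthetases (0.0208), IRE1 and XBP1s (0.0223), p53 (0.0198), NF-kappaB (0.00278) and cholesterol (0.008), and DDIT3 passed (edgeR adjusted p = 0.037). The lists it added for the drug were the stress response (0.00852), ATF6 (0.0416), interferon (0.0178), oxidative phosphorylation (0.00478), epithelial (0.0109) and endothelial (0.043) lists, and in the last comparison ATF6 (0.0114), interferon (0.0189), YAP (0.0246) and hypoxia (0.0235). The limma-voom test added oxidative phosphorylation (0.0174) and epithelial genes (0.0486) for the drug and NF-kappaB (0.0451) between genotypes, and lost no call. With a mean of at least 5 CPM, 239, 83 and 425 genes changed at least 2-fold in the 3 comparisons; that filter left 11128 genes and 232, 82 and 417 of the 1068, 585 and 1739 genes called at 2-fold without it. It added the epithelial list for the drug (0.0352) and CDK4 between genotypes (edgeR adjusted p = 0.0491). Camera with an estimated correlation called 0, 2 and 0 lists, fry called 19, 12 and 22, and the block with an estimated correlation called 1, 0 and 0. The cause of these differences between list tests was not tested.

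With the replicate block, genes that fell with the drug and were lower in the knockout numbered 853, and the calls of CDK4 and DDIT3 and the epithelial, matrix and hypoxia lists were gained as reported. Among the named genes and lists the block changed no other call. Other genes were compared by counts only, and every overlap between the first 2 comparisons was larger with the block. Of 11830 genes in windows with a median within 0.1 of 0, 2471 differed between genotypes when adjusted over those genes alone (1185 higher, 1286 lower, 279 at least 2-fold). Adjusted over all genes, 2667 of them did.

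Leaving out each library in turn gave 7357 to 8437, 4272 to 5705 and 9048 to 10354 called genes and 11 to 14, 7 to 10 and 13 to 14 lists in the 3 comparisons. Genes that fell and were lower numbered 358 to 532, against 536 with all libraries. TNFAIP6 lost its call in 6 of these, without a filter (edgeR adjusted p = 0.0885) and with only the 6 libraries compared (0.0639). In the simulation, with all 9 libraries and few changed genes, 40.8 to 50% of the smallest changes were recovered. The share recovered in the real comparisons may differ.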

Other observations

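The family screen, the search for nearly absent genes, the copy-number test, the GC content test on windows and the S phase test were chosen only after the results were seen. In wild-type cells on palbociclib, genes of splicing factors, the proteasome, the chaperonin CCT and mitochondrial ribosomes fell, each called with the preset correlation only. Of 31 SR and hnRNP splicing genes 23 fell and 0 rose (median log2 fold change -0.32, camera adjusted p = 3.5e-11, and 0.128 with an estimated correlation). Of 35 proteasome subunits 23 fell and 0 rose (median -0.22, camera adjusted p = 0.000166, and 0.365 with an estimated correlation), and 6 of 7 subunits of the chaperonin CCT fell (median -0.34, camera adjusted p = 0.000374, and 0.365 with an estimated correlation). Of 73 mitochondrial ribosomal proteins 49 fell and 2 rose (median -0.22, camera adjusted p = 3.1e-06, and 0.365 with an estimated correlation). Coat proteins of vesicles between endoplasmic reticulum and Golgi rose (15 of 27, 0 lower, median 0.15, camera adjusted p = 0.00015, and 0.305 with an estimated correlation), as did the vacuolar proton pump (10 of 19 higher, 3 lower, median 0.17, camera adjusted p = 0.00484, and 0.159 with an estimated correlation).

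In the knockout on palbociclib, 8 genes with at least 2 CPM in wild-type cells were below 5% of the wild-type level, and 0 genes showed the reverse. CDKN2B, encoding the CDK4 and CDK6 inhibitor p15 (chromosome 9, 22002903 to 22009363), had 3 counts against 828 over 3 libraries each, or 0.33% of wild type (95% interval 0.068 to 0.969%, counting error only). Its neighbours MTAP and KLHL9 had log2 fold changes of -0.02 and -0.03. The zinc finger genes ZNF93 (1 count against 284) and ZNF675 (4 against 567) and the homeobox gene ALX4 (10 against 238) were the others not yet named, beside PAGE2B, CTSB, HSPB7 and BST2. Next to CTSB, FDFT1 was lower (-1.36) and NEIL2 had a log2 fold change of 0.16. Of 27 MAGE, PAGE and GAGE genes 9 were lower and 3 higher (median 0.03, test direction down, camera adjusted p = 2.9e-05, and 0.463 with an estimated correlation). PAGE2B (-9.12), whose count is uncertain, belongs to this family, and the family was not tested without it. Of 16 GALNT glycosyltransferases 8 were higher and 1 lower (median 0.21, camera adjusted p = 0.012, and 0.664 with an estimated correlation).

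Neighbouring genes shifted together between genotypes. The window medians of strongly and of weakly expressed genes correlated at 0.837, against at most 0.21 in 1000 permutations of gene positions, and at -0.08 for the drug in wild-type cells. The median GC content and length of the genes' longest annotated transcripts explained 5.38% of the variance of window medians (95% interval over resampled windows 2.57 to 13.4%). This argues against a bias by that GC content or length as the main cause. DNA copy number or another regional difference between the knockout and parental cells may account for the regional part, and a response to PERK loss itself stays open, since copy number was not measured and genotype and cell history cannot be separated here. Stress response mRNAs kept 102% of their median after window medians were subtracted, which argues against a regional origin of that list's shift.

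Histone mRNAs were lower in the knockout. The 11 non-histone genes among the chromosome 6 histones had a median of -0.103 (95% interval -0.351 to 0.16), above the histone median of -1.02 (-1.48 to -0.62). Both intervals come from resampling the genes and leave out the spread between libraries. Of these 11 genes 2 were called lower and 2 higher, from -1.75 (HFE) to 0.557 (BTN3A2). The medians argue against a shift of the whole cluster, while a shift of part of it stays open. The S phase list had a median of 0.185, and its level over libraries, not paired by set, was higher by 0.18 (95% interval 0.0298 to 0.329). Its call was lost in the test against other genes (adjusted p = 0.89 with an estimated correlation). So mRNAs of DNA replication did not fall along with the histones. The share of cells in S phase was not measured, and fewer such cells cannot be excluded from mRNA levels. The 63 structural RNAs without a tail had a median of -0.039 (-0.182 to 0.0691 over resampled genes), from -3.21 to 1.51, so as a set they did not fall along with the histones. Reads from genes that overlap them cannot be told apart here. These values therefore do not decide whether less untailed RNA was carried over. A change in the tailed fraction of histone mRNA or in histone transcription was not tested.

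Ribosomal protein mRNAs were higher in the knockout, at a median of 0.28, a call lost with the correlation estimated (adjusted p = 0.586 with an estimated correlation). Lists were matched on expression and on the length and GC content of each gene's longest annotated transcript. They had a median of 0.0324 over 10000 draws (highest 0.156), and 91.8% of the shift was left after window subtraction. These values argue against a bias by that length or GC content, or regional shifts, as the whole cause. The expressed transcript can be shorter than the longest annotated one, and a bias by its length was not tested. The cause stays open, since loss of PERK and differences between cell populations that arose apart from it cannot be separated in this design.

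For each comparison the 6 libraries make 10 splits of 3 against 3, too few for a share under 0.05. The real splits called 7996, 5551 and 9986 genes, each 1 of 10 with as many, and the highest other split called 0 genes, among them 3 that part as many set pairs. Every other split puts libraries of both groups on each side, which widens the spread within a side. Its 0 calls therefore do not gauge chance.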
